A study of Mus musculus with 9 samples.

How the data were processed

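Liver RNA of C57BL/6 mice was extracted with Trizol and sequenced on an Illumina instrument, per the labels' protocols. The 9 libraries comprise 3 each from control mice, mice on a high-fat diet (HFD) and mice on a high-fat diet gavaged with *Papillibacter cinnamivorans* (HFD+Pc). Reads were aligned with HISAT2 2.0.5 to GRCm39, per the submitters' processing notes. The deposited table holds FPKM, per the file headers, for 54007 genes or gene models in the 9 libraries. The tool that counted reads, the annotation and the origin of 307 models without an Ensembl identifier are not stated. Of 53700 Ensembl identifiers, 52093 were named from a gene name table and 1607 stayed without a symbol. A GENCODE M21 annotation, which belongs to an earlier build than GRCm39, served only for gene lengths, GC content and copies of genes, and no coordinates are given.

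Within a gene, the deposited FPKM values were whole multiples of the value of 1 read, so reads could be recovered. Recovery succeeded for 26185 of 26278 genes above 0 (99.6%), with a tolerance of 0.02 from a whole number, and 25356 of these used the annotated length. The recovered totals were 16562012 to 18930302 per library, and it is not known whether they count reads or read pairs. The divisor behind each library's FPKM was 97.4% to 108% of its recovered total, so the authors' FPKM appear to rest on a rescaled library size, which no source states. The plan fixed before the data were examined had set a count test if whole reads could be recovered and limma on log values if not. The condition for the count test was met, but that test and its scaling were not run, since the deposited values are FPKM and not counts. This departs from the plan. Limma on the FPKM was used throughout, and limma-voom on the recovered reads was added as an alternative after the data were seen.

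Genes with at least 1 FPKM in at least 3 libraries were tested, 10988 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust estimation) on log2(FPKM + 1), with all 9 libraries in 1 model, 1 mean per group, and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Comparisons were HFD against control, HFD+Pc against HFD and HFD+Pc against control. A count was also made of genes that passed in the first and second with opposite signs, and 100 simulations with no effect or with the HFD effect alone gave values to set beside it. The HFD group of 3 cannot be divided into parts of 2 for separate comparisons.

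Before the data were examined, 34 gene lists were fixed, covering pathways, RNA quality and markers of liver and other cell types. The 29 lists with at least 5 tested genes were compared with all other genes by camera (preset correlation 0.01) on the same log2(FPKM + 1) values, in place of the log2 CPM planned, with adjustment over the lists of a comparison. Camera with an estimated correlation called 0 lists in each comparison, against 14, 7 and 11 with the preset correlation, and fry was run beside it. Genes were named by a rule fixed at the same time. It took the 10 largest rises and the 10 largest falls among genes that passed, had a mean of at least 1 FPKM, had groups that did not overlap and carried a gene name. It added from each list up to 2 passing genes per direction with the lowest adjusted p, a panel of genes of lipid, bile acid, glucose and inflammation biology whatever their result, and up to 5 genes per direction that passed with opposite signs. A few list members beyond the rule are named after their values were seen, to complete a count: Fbp1, Igfbp2, Pklr, Irs2 and Sqle.

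The test was tested on simulated data over 10758 genes with known changes. Every simulated gene had the same negative binomial dispersion (0.00672), genes were independent and no library stood apart. The rates below therefore do not hold for genes that vary more between libraries. At 1.5-fold, 2-fold and 4-fold it recovered 70.1%, 92.5% and 89.4% of changed genes for HFD against control. For HFD+Pc against HFD it recovered 65.7%, 94.0% and 97.0%, and for HFD+Pc against control 75.4%, 93.3% and 92.4%. Of unchanged genes, 15 of 10558, 9 of 10558 and 17 of 10358 were called. The median standard error over genes was 0.11 on the log2 scale.

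The alternatives tried were other scalings, pseudocounts, filters and thresholds, fits of 2 groups alone, a replicate block, and each library left out in turn. Added after the data were seen were limma-voom, FPKM from plain read totals, removal of a trend in GC content and length, and fry in either direction. Near-identical copies of 64 genes that passed in HFD+Pc against HFD were searched with BLAST 2.17.0+ at 90% identity over at least 100 bases. No share of the gene had to be covered, so a match may be a shared stretch and not a copy of the gene. Replicate numbers were not used to pair libraries, since deviations from group means correlated at -0.119 to 0.0533 between libraries of the same number. A rule for single outlying libraries was not applied, since it needs groups larger than 3. A few genes that were planned or found are not reported here.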

Results

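Liver RNA was sequenced from C57BL/6 mice at postnatal day 98, in 3 groups of 3 libraries each. The control group comprised replicates 1, 2 and 4, the high-fat diet group (HFD) replicates 1, 2 and 3, and the high-fat diet group gavaged with the bacterium *Papillibacter cinnamivorans* (HFD+Pc) replicates 1, 3 and 4. Mice entered the study at 6 weeks of age, 15 per group, and the labels do not say whether a library is 1 mouse or a pool, so the p-values measure the spread between these libraries. Each library held 16562012 to 18930302 reads as recovered from the FPKM values, and 10323 to 10587 genes reached 1 FPKM. In a gene of 1 kb, 3 reads corresponded to 0.160 to 0.179 FPKM, a floor that covers counting error only. Levels are mean FPKM ± SD (n = 3), and differences are on the log2(FPKM + 1) scale ± SE, which understates changes of low genes.

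The first principal component held 39.6% of the variance over the tested genes and ordered the groups as control, HFD and HFD+Pc. The second held 15.2% and separated HFD replicates 1 and 2 (-17.6 and -18.9) from the HFD+Pc libraries (above 0, up to 10.8). HFD replicate 3 lay between them at -3.94. Its correlation with HFD replicates 1 and 2 across genes was 0.982 and 0.980, and with the 3 HFD+Pc libraries 0.981 to 0.982.

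**Figure D1:**
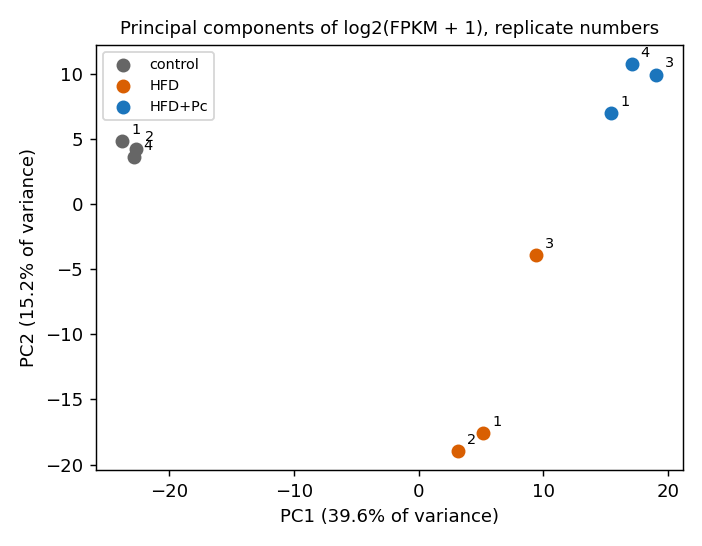
The 9 liver libraries on the first and second principal components (unitless scores) of log2(FPKM + 1), which hold 39.6% and 15.2% of the variance. Each point is 1 library with its replicate number, colored by group, and HFD replicate 3 sits between the other HFD libraries and HFD+Pc.

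The first comparison, HFD against control, asks which liver genes differ with the diet. Livers of the HFD group held more transcript for Cd36, a fatty acid uptake receptor, which rose from 20.03 ± 2.19 to 78.004 ± 17.2 FPKM (1.89 ± 0.15, limma adjusted p = 0.002502). Transcripts of glucose output fell: Pck1, the gluconeogenic PEP carboxykinase, went from 1095 ± 109 to 328 ± 30.1 FPKM (-1.73 ± 0.24, limma adjusted p = 0.006703). G6pc, the catalytic subunit of glucose-6-phosphatase, went from 325 ± 73.6 to 104 ± 14.5 FPKM (-1.61 ± 0.27, limma adjusted p = 0.0127). The metal-binding metallothionein Mt1 fell from 349.7 ± 194 to 29.9 ± 8.75 FPKM (-3.37 ± 0.57, limma adjusted p = 0.0133). Without control replicate 1 the adjusted p of Mt1 was 0.05503, whereas Cd36, Pck1 and G6pc passed in each of the 9 fits that left out 1 library.

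**Figure D2:**
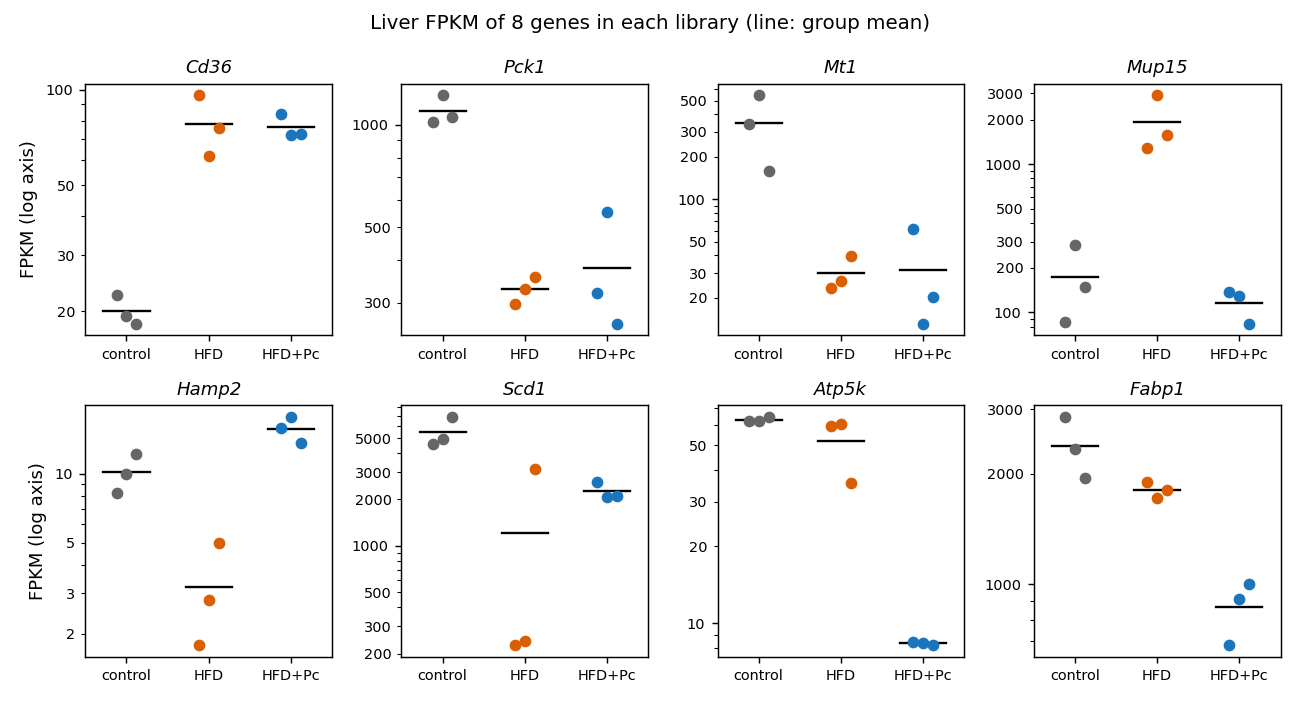
FPKM (log axis) of 8 genes in each of the 9 libraries, with 1 point per library and a line at each group mean. Cd36 was higher and Pck1 and Mt1 lower in both high-fat diet groups than in control, whereas Mup15, Hamp2, Atp5k and Fabp1 differed between HFD and HFD+Pc, and Scd1 spread widely within HFD.

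Among 23 tested genes of lipid droplets and fatty acid uptake, 4 rose and 4 fell (6 and 5 adjusted over the list alone). Besides Cd36, the triglyceride synthesis enzyme Mogat1 rose by 1.28. The nuclear receptor Pparg rose from 1.68 ± 0.5803 to 3.61 ± 0.844 FPKM, a call lost without control replicates 2 and 4 or HFD replicates 1 and 3 (highest limma adjusted p = 0.0703). G0s2, an inhibitor of triglyceride lipase, fell from 267 ± 102 to 67.6 ± 22.7 FPKM (-1.94 ± 0.31, limma adjusted p = 0.0103). Of 35 genes of fatty acid oxidation and PPAR-alpha targets, 3 rose and 2 fell (5 and 4 adjusted over the list alone). Vnn1, a pantetheinase, rose from 31.3 ± 1.07 to 77.6 ± 18.2 FPKM (1.26 ± 0.16, limma adjusted p = 0.00532). Cpt1a, which carries fatty acids toward mitochondrial oxidation, fell by 0.57 ± 0.13, and lost its call without control replicates 2 and 4 or HFD replicates 1 and 2 (highest limma adjusted p = 0.0748). Ppara (-0.07), Plin2 (0.18), Cyp4a14 (0.29), Cidec (0.87) and Fgf21 (-0.87) did not pass (limma adjusted p = 0.672, 0.433, 0.588, 0.116 and 0.0656), although Fgf21 passed without HFD replicate 3 and by voom (adjusted p = 0.00922 and 0.0338).

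In fatty acid synthesis, 3 of 23 genes fell and none rose (4 and 0 adjusted over the list alone). Scd1, the main stearoyl-CoA desaturase, averaged 5446 ± 1244 FPKM in control and 1213 ± 1697 in HFD (-3.26 ± 0.85, limma adjusted p = 0.0443). HFD replicates 1 and 2 held 226 and 241 FPKM of Scd1 and replicate 3 held 3173. The Scd1 call was lost in 8 of the 9 fits without 1 library, those without control replicates 1, 2 and 4, HFD replicates 1 and 2 or HFD+Pc replicates 1, 3 and 4 (highest limma adjusted p = 0.1303), whereas without HFD replicate 3 the difference was -4.51 (limma adjusted p = 3.90e-05). Srebf1 (0.35) and Fasn (0.29) did not pass (limma adjusted p = 0.336 and 0.752). The list ranked below other genes by camera (adjusted p = 0.0164), with adjusted p = 0.716 with an estimated correlation, and lost the first call without control replicate 4, HFD replicate 1 or HFD replicate 2 (adjusted p = 0.0609, 0.116 and 0.0669). Its level per library, relative to the mean of all 9, was -0.59, -0.38 and 0.28 in HFD replicates 1, 2 and 3. In control replicates 1, 2 and 4 it was 0.28, 0.08 and 0.27, so HFD replicate 3 was not below control.

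In cholesterol synthesis and uptake, 3 of 25 genes rose and none fell (6 and 0 adjusted over the list alone), with a median difference of 0.65. Hmgcs1, which feeds the mevalonate pathway, went from 25.9 ± 5.23 to 90.4 ± 25.97 FPKM (1.75 ± 0.32, limma adjusted p = 0.0168), and without control replicate 2 had adjusted p = 0.0639. The sterol oxidase Msmo1 rose by 1.94 and lost its call without control replicates 1, 2 and 4 or HFD replicates 2 and 3 (highest limma adjusted p = 0.0728). The camera adjusted p of the list was 0.00188, against adjusted p = 0.716 with an estimated correlation, and 0.0845 by camera without HFD replicate 3.

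Among 22 genes of glucose metabolism and insulin response, 7 fell and none rose (9 and 1 adjusted over the list alone). Besides Pck1 and G6pc these were Fbp1 (-0.53), Igfbp1 (-1.81), Igfbp2 (-0.47), Pklr (-1.15) and Irs2 (-1.04). The camera adjusted p of the list was 0.00212, against adjusted p = 0.464 with an estimated correlation. The Igfbp1 call was lost without control replicates 1 and 2 or HFD replicate 1 (highest limma adjusted p = 0.0759). In bile acid synthesis and transport, 3 of 23 genes rose and 3 fell (6 and 5 adjusted over the list alone). The export pump Abcc3 rose from 41.8 ± 4.56 to 74.7 ± 5.38 FPKM and the uptake carrier Slco1b2 by 0.64, while the carrier Slco1a4 fell from 17.3 ± 0.715 to 5.54 ± 1.59 FPKM (limma adjusted p = 0.00467, 0.00947 and 0.002502). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.04 and Nr0b2 by -0.25, neither passing (limma adjusted p = 0.948 and 0.695). Cyp8b1 fell by 0.41 ± 0.11, a call lost without control replicates 1 and 2, HFD replicates 1, 2 and 3 or HFD+Pc replicates 1, 3 and 4 (highest limma adjusted p = 0.142).

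Xenobiotic metabolism genes moved both ways, with 6 of 33 rising and 4 falling (11 and 4 adjusted over the list alone). Cyp2b10 rose from 2.36 ± 1.33 to 13.999 ± 7.82 FPKM, a call lost without control replicates 1 and 2 (highest limma adjusted p = 0.0569). The aryl hydrocarbon receptor Ahr rose by 0.60, and the glutathione transferase Gstm2 fell from 57.1 ± 11.6 to 17.8 ± 2.64 FPKM (limma adjusted p = 0.00943 and 0.00773). On the log2(FPKM + 1) scale the gene with the largest rise was Mup15, a major urinary protein, from 173 ± 103 to 1921 ± 881 FPKM (3.54 ± 0.44, limma adjusted p = 0.00532). Reads of Mup15 and of the related Mup1, Mup9 and Mup11 cannot be assigned with certainty, since Mup15 had 18 near-identical copies. Of 30 tested acute phase and inflammation genes 2 rose and none fell (1 and 0 adjusted over the list alone), Il1rn by 0.61 and Saa4 by 0.82. The Il1rn call was lost in 2 of the 6 fits without 1 library in which it passed the filter and the Saa4 call in 8 of 9 (highest limma adjusted p = 0.0703 and 0.123). Ccl2, Tnf, Il6 and Tlr4 averaged 0.385, 0.1295, 0.0374 and 0.809 FPKM in HFD and, like the lipid droplet gene Cidea (1.08 FPKM), were below the filter. Saa1, an acute phase protein, differed by 0.60 ± 1.63 (limma adjusted p = 0.845).

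Markers of other cells and of RNA quality moved as well. Of 12 endothelial markers 4 fell and none rose (9 and 0 adjusted over the list alone), Kdr by 0.63 and Stab2 by 0.51, both lost without control replicate 2 (limma adjusted p = 0.0501 and 0.0539). The camera adjusted p of this list was 2.60e-05, against adjusted p = 0.464 with an estimated correlation. Igkc and Jchain, markers of plasma cells, rose by 1.41 and 0.91 (limma adjusted p = 0.00788 and 0.0138). Cfd, an adipocyte marker, rose from 0.0812 ± 0.0706 to 12.3 ± 8.55 FPKM (3.42 ± 0.43, limma adjusted p = 0.00532). Both lists, B and plasma cell and adipocyte markers, had camera adjusted p = 0.0201 and adjusted p = 0.464 with an estimated correlation, the first lost without control replicate 4 or HFD replicate 1 and with plain read totals (adjusted p = 0.0832, 0.08503 and 0.0567). Among immediate early genes, which respond to handling, 3 of 13 fell and none rose (10 and 1 adjusted over the list alone), with a median of -0.75. Its camera adjusted p was 0.000706, against adjusted p = 0.464 with an estimated correlation.

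Of 46 cytosolic ribosomal proteins 5 fell and none rose (10 and 0 adjusted over the list alone) and 44 had a negative difference (median -0.25), and of 41 oxidative phosphorylation genes 6 fell and none rose (6 and 0 adjusted over the list alone). By camera these lists had adjusted p = 2.35e-06 and 8.28e-05, and both had adjusted p = 0.620 with an estimated correlation. Of 19 hepatocyte markers 1 fell and none rose (7 and 0 adjusted over the list alone) and 16 had a negative difference (median -0.34). The gene that fell was Apoa1 (-0.77), whose call was lost without control replicates 1, 2 and 4, HFD replicates 1 and 3 or HFD+Pc replicate 3 (highest limma adjusted p = 0.113). Of 10 stellate cell markers Cygb (-0.46) and Ecm1 (-0.58) fell and none rose (5 and 1 adjusted over the list alone), the first lost without control replicate 2 and the second without control replicates 2 and 4 or HFD replicates 1 and 3 (highest limma adjusted p = 0.0539 and 0.0857). By camera, hepatocyte and stellate cell markers had adjusted p = 0.00188 and 0.0161, and both had adjusted p = 0.464 with an estimated correlation. By fry, which tests whether the genes of a list move on balance one way, hepatocyte, endothelial and stellate cell markers and the glucose list passed (adjusted p = 0.0349, 0.0349, 0.0393 and 0.0349). Of 14 antigen presentation genes 4 fell and none rose (5 and 0 adjusted over the list alone), and of 19 sex-biased liver genes 2 rose and none fell (5 and 1 adjusted over the list alone). Their camera adjusted p values were 0.01002 and 0.00549, against adjusted p = 0.620 for both with an estimated correlation, the first lost without HFD replicate 3 and the second without HFD replicate 2 or with no filter (adjusted p = 0.08198, 0.114 and 0.05395). The sex-biased list was not split by the sex with the higher level, so its direction has no reading for either sex. Its level in HFD replicate 1 (-0.24) lay within those of control replicates 1, 2 and 4 (-0.21, -0.14 and -0.47).

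By limma, 1095 of 10988 tested genes passed, 507 higher and 588 lower in HFD, and 119 of them differed at least 2-fold. At an unadjusted p under 0.05, 3052 genes passed, and the 2 groups did not overlap in 32.9% of tested genes, against 10% by chance. The count was 349, 332 and 576 without control replicates 1, 2 and 4, and 482, 606 and 578 without HFD replicates 1, 2 and 3, and 26 of 81 named genes that passed did so in every fit without 1 library. It was 659 with only the 2 groups compared, 725 with a minimum of 0.1 FPKM and 209 with no filter.

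**Figure D3:**
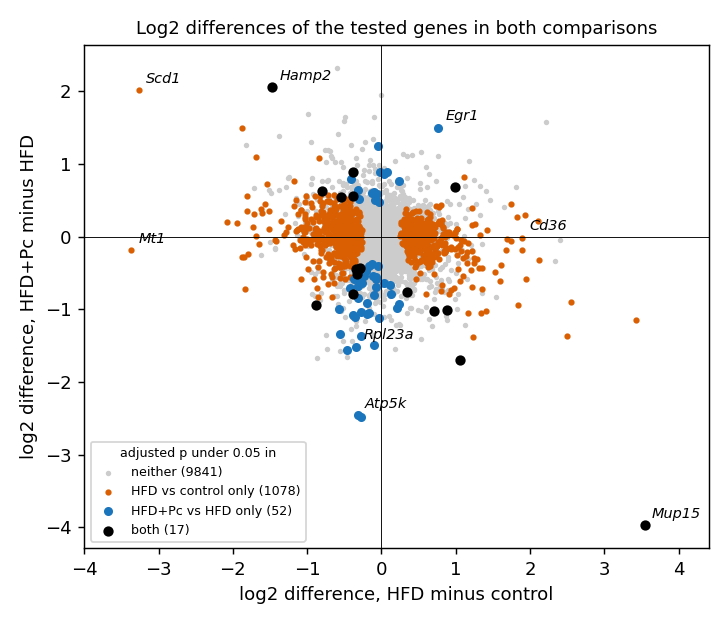
Log2 differences of each tested gene in HFD against control (x axis) and in HFD+Pc against HFD (y axis), both on the log2(FPKM + 1) scale, colored by which comparison passed limma at an adjusted p under 0.05. Genes that passed in HFD against control lie along the x axis, and 10 genes passed in both with opposite signs.

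The second comparison, HFD+Pc against HFD, asks which liver genes differ with gavage of the bacterium on the same diet. Hamp2, a hepcidin-type peptide gene, rose from 3.19 ± 1.65 to 15.7 ± 2.05 FPKM (2.06 ± 0.25, limma adjusted p = 0.0138), with 10.1 ± 1.95 in control. Its near-identical copy held far more reads and was lower in HFD+Pc, and recovered reads summed over both differed by -1.36. Atp5k, a subunit of the mitochondrial ATP synthase, fell from 51.7 ± 14.2 to 8.32 ± 0.139 FPKM (-2.46 ± 0.17, limma adjusted p = 0.00147). Fabp1, the liver fatty acid binding protein, fell from 1808 ± 89.8 to 865 ± 165 FPKM (-1.08 ± 0.18, limma adjusted p = 0.0452). Mup15 fell from 1921 ± 881 to 116 ± 28.6 FPKM (-3.97 ± 0.44, limma adjusted p = 0.0119), whereas recovered reads summed over Mup15 and its 18 near-identical copies differed by -0.40.

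The other named rises were Egr1, an immediate early transcription factor, from 2.32 ± 0.795 to 8.25 ± 1.16 FPKM, the endoplasmic reticulum chaperone Dnajb9 from 21.9 ± 2.53 to 37.9 ± 3.15 FPKM, and Rps19bp1 from 5.77 ± 0.104 to 11.5 ± 0.671 FPKM (limma adjusted p = 0.0446, 0.0244 and 0.00869). Tap2, a peptide transporter of antigen presentation, rose by 0.54, the proteasome subunit Psmb5 by 0.50, the ribosomal protein Rpl10 by 0.58, Tmem53 by 0.56, Atp5g1 by 0.51 and the transcript Hectd2os by 0.69. Falls included the ribosomal proteins Rpl23a (-1.51), Rps29 (-1.10) and Rpl41 (-0.99), the complex I subunit Ndufa3 (-1.07), the mitochondrial ribosomal protein Mrps21 (-1.06), Ugt2b37 (-0.76) and the immunoglobulin heavy chain gene Igha (-1.01). Of 49 genes that fell, 24 were under 1000 bases long (49.0%, against 9.74% of tested genes). The genes that rose were short as well, with a median length of 1457.5 bases, against 1022 for the falls and 3856.5 for tested genes. Near-identical copies that held more reads than the gene make the reads of Hamp2 and Ugt2b37 uncertain. Atp5g1 matched 560 other genes over at least 100 bases, which may be shared stretches and not copies, so its reads are uncertain as well. Reads summed with the copies differed by -1.36 for Hamp2, -0.92 for Rpl23a and -0.62 for Rpl41. By the same measure the genes alone differed by 2.30, -1.59 and -0.99.

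With all libraries, no gene of the lipid and glucose panel that rose or fell with the diet passed here. Cd36 differed by -0.02 ± 0.15, Pck1 by 0.13 ± 0.24 and G6pc by 0.32 ± 0.27 (limma adjusted p = 0.974, 0.832 and 0.623). Scd1 differed by 2.01 ± 0.85, Pparg by 0.17 ± 0.17, Cpt1a by -0.07 ± 0.13 and Cyp8b1 by 0.06 ± 0.11 (limma adjusted p = 0.295, 0.673, 0.8402 and 0.816). HFD replicate 3 decides the result for Scd1: without it the difference was 3.27 (limma adjusted p = 0.000305). Srebf1 (-0.17), Fasn (0.59), Plin2 (0.22), Cidec (-1.09), Ppara (0.24), Cyp4a14 (0.18), Fgf21 (0.51), Cyp7a1 (-0.54), Nr0b2 (0.85) and Saa1 (-0.97) did not pass either (lowest limma adjusted p = 0.157, for Cidec), although Fgf21 had adjusted p = 0.04803 without HFD replicate 3.

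Of 16 tested macrophage markers none passed, by adjustment over all genes or over the list alone, and 15 had a negative difference (median -0.41). The list ranked below other genes by camera (adjusted p = 7.22e-05), with adjusted p = 0.7099 with an estimated correlation. Its level per library, relative to the mean of all 9, was -0.40 and -0.53 in HFD+Pc replicates 3 and 4 and 0.08 in replicate 1, against 0.24, 0.27 and -0.07 in HFD replicates 1, 2 and 3. No gene of cholesterol synthesis and uptake passed (1 higher adjusted over the list alone). That list had a median of 0.33, a camera adjusted p of 0.0333, and adjusted p = 0.808 with an estimated correlation. Its camera call was lost without HFD replicate 1 or HFD+Pc replicates 3 or 4 (adjusted p = 0.246, 0.07498 and 0.4495). Camera also called adipocyte (-0.36), B and plasma cell (-0.36) and erythroid markers (-0.42), interferon response (-0.11) and mitochondrially encoded genes (0.40), given as medians (adjusted p = 0.0333, 0.0333, 0.0405, 0.0333 and 0.0359). With an estimated correlation these had adjusted p = 0.708, 0.708, 0.708, 0.808 and 0.7099, and each lost its camera call without HFD replicate 1 (adjusted p = 0.0561, 0.113, 0.0847, 0.382 and 0.0561) and in other fits. The level of mitochondrially encoded genes per library was -0.29, -0.32 and 0.24 in HFD replicates 1, 2 and 3. In HFD+Pc replicates 1, 3 and 4 it was 0.16, 0.17 and 0.19, so HFD replicate 3 lay above each of them. Reads of all mitochondrial genes made up 7.51 ± 1.28% of recovered reads in HFD and 6.95 ± 0.332% in HFD+Pc. As many or more lists were called by camera in 7 of the 10 splits of these 6 libraries, the real one included.

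By limma, 69 of 10988 genes passed, 20 higher and 49 lower in HFD+Pc (17 and 98 with plain read totals, 59 and 73 with the trend in GC content and length removed), and 28 of the 69 had a provisional or pseudogene symbol or no symbol. At an unadjusted p under 0.05, 1718 genes passed, and the groups did not overlap in 19.8% of tested genes. The count was 23, 32 and 28 without control replicates 1, 2 and 4, 26, 5 and 123 without HFD replicates 1, 2 and 3, and 25, 7 and 12 without HFD+Pc replicates 1, 3 and 4. It was 3 with no filter, 27 with a minimum of 0.1 FPKM and 22 with the 2 groups alone, and of the 23 passing genes followed one by one only Atp5k, Rps19bp1 and 1 unannotated transcript model passed in every fit without 1 library. The call was lost in 3 such fits for Mup15, 4 for Hamp2, 6 for Egr1 and Tap2, 7 for Fabp1 and all 9 for Rpl10, Rpl41, Tmem53, Atp5g1 and Hectd2os.

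Of the 1095 genes that differed with the diet, 10 also passed in HFD+Pc against HFD with the opposite sign and 7 with the same sign. Up with the diet and down with the bacterium were Mup15, Igha, Ugt2b37, Gm13131 and 1 unannotated transcript model. Down with the diet and up with the bacterium were Hamp2, Tap2, Tmem53, Rps19bp1 and Gm4737. Near-identical copies held more reads than the gene for 5 of the 10, Mup15, Hamp2, Ugt2b37, Gm13131 and Gm4737, and reads summed with the copies differed by -0.40, -1.36, 0.09, -0.02 and 0.23 in HFD+Pc against HFD. Tap2 averaged 4.02 ± 0.195 FPKM in control, 2.42 ± 0.0839 in HFD and 3.99 ± 0.368 in HFD+Pc. Both comparisons share the HFD libraries, which produces opposite signs by itself, so the count was compared with simulations. Groups simulated with no effect gave a mean of 0.01 genes, those with the HFD effect alone gave 0.11, and independent lists of these sizes would share 3.33. For the 7 genes with the same sign these values were 0, 0.02 and 3.545. The simulated groups hold no difference between HFD+Pc and HFD, so few genes pass and both simulated counts lie near 0 by construction, and they do not show whether more genes moved back than the shared libraries produce.

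Across genes, which are not independent replicates, the correlation of the differences in HFD against control and in HFD+Pc against HFD was -0.121, against -0.502 in simulations with no effect and -0.218 with the HFD effect alone. The covariance was -0.0100, against -0.0124 with no effect and -0.0125 with the HFD effect alone. Opposite signs were found in 53.8% of the 1095 genes, against 63.2% with the HFD effect alone. Simulations with the HFD effect alone start from the observed means, which already hold noise, so no conclusion is drawn from their values. The 507 genes up with the diet had a median difference of 0.49 in HFD and 0.49 in HFD+Pc, each against control, and the 588 genes down had -0.52 and -0.49. These genes were chosen by their difference in HFD, and both differences share the control libraries. The medians therefore do not show how much of the diet effect remained in HFD+Pc. The 10 became 20 without HFD replicate 3, 1 without HFD replicate 2 and 2 without HFD+Pc replicate 3 or 4. It was 5, 5 and 6 without control replicates 1, 2 and 4, 6 without HFD+Pc replicate 1, 3 from fits of 2 groups alone and 0 with no filter.

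The third comparison, HFD+Pc against control, asks how the livers of gavaged mice on the high-fat diet differ from those of control mice. Cd36 was 76.2 ± 6.88 FPKM in HFD+Pc against 20.03 ± 2.19 in control (1.88 ± 0.15, limma adjusted p = 0.000954). Hmgcs1 rose to 129 ± 52.97 FPKM (2.19 ± 0.32, limma adjusted p = 0.00356) and Cyp2b10 to 14.9 ± 0.752 FPKM (2.32 ± 0.37, limma adjusted p = 0.00417). Pck1 fell to 379 ± 156 FPKM (-1.60 ± 0.24, limma adjusted p = 0.00356) and Mt1 to 31.7 ± 26.2 FPKM (-3.55 ± 0.57, limma adjusted p = 0.004403). Atp5k fell from 62.96 ± 1.37 to 8.32 ± 0.139 FPKM (-2.78 ± 0.17, limma adjusted p = 0.000247).

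In cholesterol synthesis and uptake, 11 of 25 genes rose and none fell (14 and 0 adjusted over the list alone), with a median of 0.92. Among them were Msmo1 (2.24), Idi1 (2.02), the squalene epoxidase Sqle (1.65) and Stard4 (1.18). The camera adjusted p of the list was 0.000132, against adjusted p = 0.711 with an estimated correlation. The level of the list per library was -0.31 in HFD+Pc replicate 1 and 0.58 and 0.88 in replicates 3 and 4, against -0.26, -0.76 and -0.63 in control replicates 1, 2 and 4.

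Of 33 xenobiotic metabolism genes 15 rose and 4 fell (16 and 4 adjusted over the list alone), including rises of Cyp2b9 (2.48), Cyp2c29 (0.86) and Ahr (0.69) and falls of Por (-1.26), the electron donor of cytochromes P450, and Cbr1 (-1.01). The camera adjusted p of this list was 0.0375, against adjusted p = 0.711 with an estimated correlation. By camera it was lost without control replicate 4 or HFD+Pc replicates 1 or 4 (adjusted p = 0.0645, 0.0618 and 0.0688), with quantile normalization (0.0921) and with the trend in GC content and length removed (0.165, median 0.25 against 0.44). In the unfolded protein and amino acid response, 7 of 22 genes rose and 3 fell (9 and 3 adjusted over the list alone). The chaperones Hspa5 (0.93) and Dnajb9 (1.01) rose, and the transcription factor Atf4 fell (-0.81). The camera adjusted p was 0.0212, against adjusted p = 0.711 with an estimated correlation, and was 0.0814 without control replicate 4 and 0.0688 without HFD+Pc replicate 4.

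Of 23 genes of lipid droplets and fatty acid uptake, 5 rose and 5 fell (6 and 5 adjusted over the list alone). Pparg rose by 0.96, while Fabp1 fell by 1.46 and the triglyceride lipase Pnpla2 by 1.07 (limma adjusted p = 0.00557, 0.00156 and 0.002004). In glucose metabolism and insulin response, 7 of 22 genes fell and none rose (7 and 0 adjusted over the list alone), G6pc by 1.29 and Pklr by 1.06. By camera that list had adjusted p = 0.0212, and adjusted p = 0.711 with an estimated correlation, with the camera call lost without control replicate 4 or HFD+Pc replicate 1 (adjusted p = 0.0508 and 0.0618). Of 35 genes of fatty acid oxidation and PPAR-alpha targets 7 rose and 1 fell (7 and 1 adjusted over the list alone). Camera gave adjusted p = 0.0212, lost without control replicate 4 (adjusted p = 0.0814), and adjusted p = 0.711 with an estimated correlation. Cpt1a fell by 0.64, and Vnn1 and Abcc3 rose by 1.43 and 0.86. Scd1 (-1.25), Srebf1 (0.18), Fasn (0.87), Plin2 (0.40), Cidec (-0.22), Ppara (0.17), Cyp4a14 (0.47), Fgf21 (-0.36), Cyp7a1 (-0.58), Nr0b2 (0.59) and Saa1 (-0.37) did not pass (lowest limma adjusted p = 0.0636, for Plin2). Scd1 passed without HFD replicate 3 and with the 2 groups alone (limma adjusted p = 0.00285 and 0.00547), Plin2 without HFD replicate 2, with the 2 groups alone and by voom (0.0293, 0.0351 and 0.0395), and Cyp7a1 without control replicate 4 (0.0238). Cyp8b1 fell by 0.34 ± 0.11, lost without control replicates 1 and 2, HFD replicates 1, 2 and 3 or HFD+Pc replicates 1, 3 and 4 (highest limma adjusted p = 0.151).

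Among immune markers, the complement gene C1qa fell by 1.18, the interferon regulator Irf7 by 1.33 and the class I gene H2-D1 by 0.74 (limma adjusted p = 0.00781, 0.00916 and 0.0056996). Of 32 interferon response genes 6 fell and none rose (5 and 0 adjusted over the list alone). Of 16 macrophage markers 3 fell and none rose (2 and 0 adjusted over the list alone). By camera these lists had adjusted p = 0.0253 and 0.0212, each lost without control replicate 4 or HFD+Pc replicate 4 and the first also without HFD+Pc replicate 3, and both had adjusted p = 0.711 with an estimated correlation. Of 12 endothelial markers Cdh5 (-0.55) and Oit3 (-0.32) fell and none rose (5 and 0 adjusted over the list alone), with a median of -0.28, and the Oit3 call was lost in 8 of the 9 fits without 1 library (highest limma adjusted p = 0.134). Camera gave that list adjusted p = 0.0253, lost without control replicate 4 or HFD+Pc replicate 4 (adjusted p = 0.0814 and 0.0688), and adjusted p = 0.711 with an estimated correlation.

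Genes of the translation and respiration machinery fell more often than they rose, as in HFD against control: of 46 cytosolic ribosomal proteins 14 fell and 1 rose, adjusted over the list alone 14 and 1, and of 41 oxidative phosphorylation genes 12 fell and 2 rose (13 and 2 adjusted over the list alone). Examples were Rps29 (-1.46), Rps15 (-1.07), Ndufb8 (-0.96) and Ndufa5 (-0.67). By camera these lists had adjusted p = 0.01102 and 0.0212, and both had adjusted p = 0.711 with an estimated correlation. The first call was lost without control replicate 1 or HFD+Pc replicate 1 (adjusted p = 0.0684 and 0.0529), and the second without control replicate 4 or HFD+Pc replicate 1 and with the trend in GC content and length removed (adjusted p = 0.0593, 0.0862 and 0.0615). Egr1 rose by 2.26, whereas 7 of 13 immediate early genes fell (9 adjusted over the list alone), among them Jund (-0.92) and Klf2 (-1.02), with a camera adjusted p of 0.01102 and adjusted p = 0.711 with an estimated correlation.

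**Figure D4:**
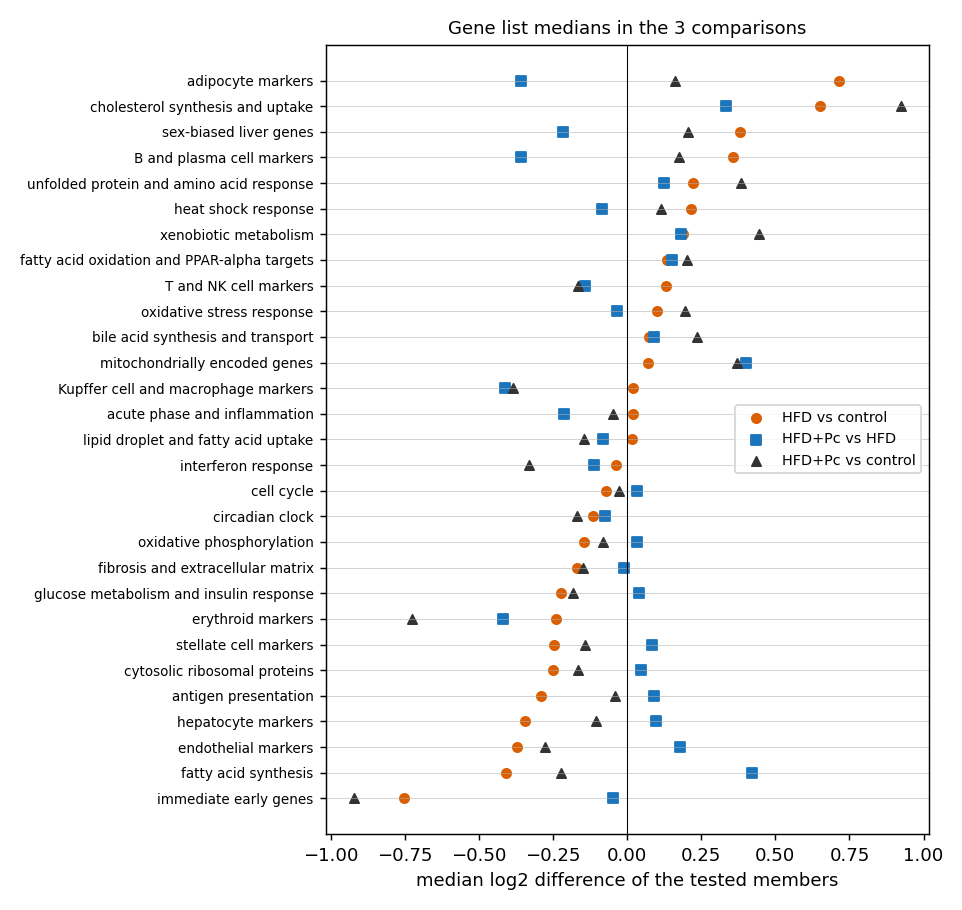
Median log2 difference of the tested members (x axis, log2 of FPKM + 1) for the gene lists (y axis), with 1 marker shape and color per comparison. Cholesterol synthesis and uptake had medians of 0.65, 0.33 and 0.92 in HFD against control, HFD+Pc against HFD and HFD+Pc against control.

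By limma, 2538 of 10988 genes passed, 1225 higher and 1313 lower in HFD+Pc, 218 of them at least 2-fold. At an unadjusted p under 0.05, 4194 genes passed, and the groups did not overlap in 42.8% of tested genes, against 10% by chance. Of the 1095 genes of HFD against control, 859 passed here with the same sign, where independent lists would share 127 and part of the excess may come from the shared control libraries. Simulations with no effect gave 0.01, where almost no gene passes, and those in which HFD+Pc keeps the HFD effect unchanged gave 1698.7 (1615 to 1787). The latter start from the observed means, which already hold noise, and add noise again. Their 1698.7 exceeds the 1095 genes of the real list, so it is no expected value for the 859. The correlation of the differences across genes was 0.762, against 0.498 with no effect and 0.906 with the HFD effect alone, and the covariance 0.0967, against 0.0123 and 0.119. The values 0.906 and 0.119 hold the same added noise, so they do not show that part of the HFD effect was lost. The count was 1660 and 1557 without control replicates 1 and 2, 1396 without HFD+Pc replicate 3 and 1383 with no filter, and 69 of 99 named genes that passed did so in every fit without 1 library.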

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

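Voom, plain totals, trend removal and fry in either direction were chosen after seeing the data. A stricter threshold lowers a count by itself, and other causes were not tested. Leaving out 1 library leaves fewer libraries, but the count also depended on which one was left out. In HFD+Pc vs HFD it was 26, 5 and 123 without HFD replicates 1, 2 and 3. Of single-gene results under the alternatives, 4728 kept direction and side of the threshold, 1115 fell below it, 13 rose above it and 24 changed sign. The 24 were values of 15 results that did not pass under either setting (lowest adjusted p 0.588). Without 1 library, log2 differences in HFD vs control were -0.143 to 0.631 for Fasn, -0.03903 to 0.681 for Cyp4a14, -0.437 to 0.234 for Cyp7a1, -0.588 to 0.126 for Nr0b2 and -0.612 to 2.096 for Saa1, in HFD+Pc vs HFD -0.3303 to 0.0688 for Srebf1, -0.167 to 0.146 for Cd36, -0.181 to 0.0351 for Cpt1a, -0.208 to 0.512 for Cyp4a14, -0.181 to 0.364 for Pck1 and -2.06 to 0.243 for Saa1, and in HFD+Pc vs control -0.462 to 0.0831 for Cidec and -1.45 to 1.12 for Saa1. With plain totals, Ppara (0.00478) and Cyp7a1 (0.0325) in HFD vs control and Cyp8b1 (-0.0125) in HFD+Pc vs HFD changed sign, as did Cyp4a14 in HFD+Pc vs HFD with a replicate block (-0.0681). Of list results, 639 kept theirs and 65 fell below. Scaling by relative log expression and scaling without the 20 most abundant genes kept all 3 gene counts within 1.5 times. The DESeq2 Wald test, the edgeR fits and TMM scaling that had been planned for counts were not run, since the deposited values are FPKM. Reads could be recovered, so this departs from the plan. Voom gave 1375, 115 and 2779 genes in HFD vs control, HFD+Pc vs HFD and HFD+Pc vs control. With plain totals, 69.3% of the 1195 genes called in HFD vs control were higher, against 46.3% of 1095, and the median of all genes moved to 0.06.

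HFD vs control (1095) gave 209 with no filter, 725 with a minimum of 0.1 FPKM, 659 with 2 groups, 119 at a log2 change of at least 1, 129 at an adjusted p under 0.01, and 332 to 1126 without 1 library. HFD+Pc vs HFD (69) gave 120 by upper-quartile scaling, 107 by quantile normalization, 3 with no filter, 27 with a minimum of 0.1 FPKM, 22 with 2 groups, 20 at a log2 change of at least 1, 5 at an adjusted p under 0.01, 115 by voom, 115 with plain totals, 132 with the trend removed, and 5 to 123 without 1 library. HFD+Pc vs control (2538) gave 1383 with no filter, 218 at a log2 change of at least 1, 836 at an adjusted p under 0.01, and 1396 to 2644 without 1 library. Genes that moved back (10) were 0 with no filter, 3 with 2 groups, 3 at a log2 change of at least 1, 0 at an adjusted p under 0.01, and 1 to 20 without 1 library.

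With the replicate number as a replicate block, counts were 232, 3 and 1058, with 1 gene moved back, although the numbers did not pair the libraries and the block takes 3 degrees of freedom. Of the lists called by camera, the block ended the calls of cholesterol synthesis and uptake in HFD+Pc vs HFD (adjusted p 0.174, median 0.156 against 0.334) and fatty acid oxidation and PPAR-alpha targets in HFD+Pc vs control (adjusted p 0.1404, median 0.0761 against 0.202).

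Lists called by camera (14, 7 and 11) were 0, 0 and 0 with an estimated correlation, 4, 0 and 1 by fry, and 22, 12 and 26 by fry in either direction. HFD+Pc vs HFD gave 12 by voom, 3 with plain totals and 3 to 10 without 1 library. HFD+Pc vs control gave 17 with no filter and 3 to 12 without 1 library.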

Other observations

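Clock genes and stress genes were among those that differed between the diets. In HFD against control, of 14 circadian clock genes 2 rose and 3 fell (2 and 3 adjusted over the list alone). Nr1d1, a repressor within the clock, rose by 0.93, a call lost without control replicate 2 or HFD replicates 1 and 2 (highest limma adjusted p = 0.06398). The labels do not give the hour of collection. Of 15 heat shock genes 3 rose and none fell (4 and 0 adjusted over the list alone), Hspb1 by 1.17 and Dnaja1 by 0.50. By camera this list had adjusted p = 0.01002, and adjusted p = 0.464 with an estimated correlation. The antioxidant enzyme Prdx1 rose by 0.54 in HFD against control and by 0.55 in HFD+Pc against control, the first lost without control replicates 1 and 2 (highest limma adjusted p = 0.0626).

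In HFD+Pc against control, of 10 stellate cell markers 1 rose and 4 fell (1 and 4 adjusted over the list alone). Lrat, which stores retinol as ester, rose from 3.58 ± 0.733 to 6.77 ± 0.948 FPKM, while Cygb fell by 0.55 and Colec11 by 0.61 (limma adjusted p = 0.00557, 0.00403 and 0.0119). Of 15 fibrosis and extracellular matrix genes 3 fell and none rose (3 and 0 adjusted over the list alone), among them Tgfb1 by 0.56. Of 6 erythroid markers 3 fell and none rose (4 and 1 adjusted over the list alone), Hba-a2 by 0.95 and Hbb-bt by 0.75, both lost without control replicates 1 or 4 (highest limma adjusted p = 0.0742 and 0.0571). Of 13 mitochondrially encoded genes mt-Co2 rose by 0.74 and mt-Nd6 by 0.67 (2 and 0 adjusted over the list alone), calls lost without control replicates 1 or 4, among others (highest limma adjusted p = 0.0639 and 0.103).

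Of the tests below, the split of the copies by their reads and the length of 1000 bases were chosen after the result was seen. Short genes were over-represented among the falls in HFD+Pc against HFD (24 of 49 under 1000 bases). Short length was not particular to the falls: the median was 1022 bases for falls and 1457.5 for rises, against 3856.5 for tested genes. A length trend over all genes is argued against: 97.7% of the 44 falls with a known GC content stayed lower after a trend in GC content and length was removed. These included all 19 short falls with a known GC content, while the falls left out were all short. Length and change correlated at a rho of 0.0613 over genes that did not pass. An effect confined to the shortest genes was not tested. Reads shared with near-identical copies stay open as a candidate explanation for 12 of the 24, whose copies hold more reads than the gene, so that the sum of both may hide the gene's change with or without sharing. In 10 of the 12 the summed change was under 0.5 of the gene's own, whereas in Gm10443 and Gm9385 it was 1.03 and 0.602, which does not point to sharing. Over the 16 short falls with copies, the summed change was a median 0.337 of the gene's own, and over all 41 passing genes with copies 0.329. The latter met the bound of 0.5 set beforehand for this cause, but the copies of 26 of the 41 hold more reads than the gene, a weakness recognised only after the result was seen. The 41 include Atp5g1 and Nfu1, whose 560 and 362 matches of at least 100 bases may be shared stretches and not copies. Over the passing falls and rises with copies, the medians were 0.371 and 0.211. For Fabp1, Ndufc2 and Gm12473 no copy with reads was found, and 5 of the 24 were not searched. In the 4 short genes with more reads than their copies, Atp5k, Mrps21, Rps29 and Rpl23a, the median was 0.974 (lowest 0.583), which argues against sharing as the whole cause there, whereas reads dropped for mapping to several places were not tested, and the gavage itself remains an untested biological explanation.

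HFD replicate 3 stood apart from HFD replicates 1 and 2. On 200 genes chosen without it, it lay at a median position of 0.437, with 0 at HFD and 1 at HFD+Pc, where left-out HFD+Pc libraries lay at 0.712 to 0.939 and left-out HFD replicates 1 and 2 at 0.305 and 0.238. That position argues against an HFD+Pc liver under an HFD label, while a mixture of samples was not tested. Blood or immune cell content cannot be told apart from other differences. Against the mean of HFD replicates 1 and 2, neutrophil markers were higher by 0.87 in replicate 3 (log2, 3 genes). Their levels were 0.67, -0.26 and 1.08 in HFD replicates 1, 2 and 3, so replicates 1 and 2 differed widely as well. Erythroid and macrophage markers of replicate 3 differed from that mean by -0.06 and -0.32. Differences between animals of 1 group are open as well, and no biological explanation was tested.

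More genes passed in HFD+Pc against control than in HFD against control, by a ratio of 2.32. Removing the trend in GC content and length gave a ratio of 2.69, which argues against that trend as the cause. With HFD replicate 3 left out of 1 count and each HFD+Pc library out of the other, the ratio was 2.42 to 3.61. This argues against that replicate as the whole cause. Its spread enters both main counts, since 1 variance per gene is fitted over all groups, and it stayed in the fits without an HFD+Pc library. With the 2 groups alone, where it enters only HFD against control, the counts were 659 and 2455. A batch of library preparation that follows the groups may account for the larger count, but the labels give no batch, so this was not tested. An added effect of the gavage is an equally untested hypothesis.

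With 3 libraries against 3 there are 10 splits, so no share under 0.1 can be reached, and only the values are given. For genes, the real split and the highest other split gave 1095 and 0 in HFD against control, 69 and 4 in HFD+Pc against HFD, and 2538 and 0 in HFD+Pc against control. Genes moved back were 10 in the real split and at most 4 in another. In each of these, 1 of 10 splits, the real one, gave as many. For lists called by camera the values were 14 and 11, 7 and 12, and 11 and 12, and as many or more were called in 1, 7 and 2 of the 10 splits.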
